A study of Homo sapiens with 2 samples.

How the data were processed

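Small RNA libraries from MDA-MB-231, an established human triple-negative breast cancer cell line, were sequenced after transduction with an shRNA against ELOVL5 (shELOVL5) or with the control shRNA named shLuc. ELOVL5 is a fatty acid elongase of polyunsaturated fatty acids. There was 1 library per condition. Per the labels' protocols, total RNA was purified with a Qiagen miRNeasy micro kit, libraries were made with a NEBNext small RNA kit, and single-end reads came from an Illumina NextSeq. The labels' extraction text mentions frozen tumor material, while the sample labels and the growth protocol describe the cell line. The labels describe no unique molecular identifiers, so PCR copies of a molecule may be counted more than once.

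The deposited values were raw read counts per mature microRNA and precursor, as the authors left them, with no normalization. FastQC 0.11.9, cutadapt 2.10 and Bowtie 1.1.1 are named in the submitters' processing notes, without their settings. The counting program, the microRNA annotation release, the mismatch setting and the treatment of reads that match several microRNAs are not given in the sources used here. The table held 2886 lines for 2656 mature microRNAs. Of these, 166 were listed under more than 1 precursor. Among the 38 such microRNAs with at least 100 counts over both libraries, the copies differed by no more than 10% in 30 and by more in 8. One value per mature microRNA was therefore kept, the highest of its copies, so that reads were not counted again for each precursor. Mature microRNAs of near-identical sequence (let-7, miR-30, miR-17 and miR-106a, miR-27a and miR-27b, miR-146a and miR-146b) may still share reads.

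After this step the shELOVL5 library held 6811811 counts and the shLuc library 7109272. Counts were scaled to counts per 1000000 counts (CPM) with TMM factors from edgeR 4.0.16 (R 4.3.3). The factors were 1.01 for shELOVL5 and 0.988 for shLuc. A microRNA was called expressed when its unscaled mean CPM over both libraries was at least 50 and its count over both was at least 100. This held for 191 microRNAs, which took 99.5% of the shELOVL5 counts and 99.6% of the shLuc counts.

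With 1 library per condition no difference can be tested against variation between cultures, and no p-value is given. For each microRNA the ratio of scaled CPM (shELOVL5 over shLuc) is given with a 95% interval from the exact Clopper-Pearson interval of 1 library's share of both counts. Such intervals, those of shares, and the limits for zero counts cover counting error only. A count of 0 allows up to 3 counts, or 0.440 CPM in shELOVL5 and 0.422 CPM in shLuc. Differences were described by a fixed rule of size, at least 2-fold.

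A total of 18 microRNA lists was fixed beforehand, covering families, genomic clusters, breast cancer, lipid metabolism, p53 and markers of other cell types. For the 12 lists with at least 3 expressed members, the median log2 ratio was set against 10000 random lists of the same size matched on mean expression in 10 bins. The difference from the median of the random lists is called the excess. Named microRNAs were those at least 2-fold different with at least 200 counts over both libraries (at most 10 per direction), the 8 most abundant, miR-210-3p, and for each list its 3 most abundant expressed members plus at most 1 more that was 2-fold different. Any other microRNA named is marked as chosen after its values were seen. The lists, the rules and all alternatives but 2 were chosen before the data were examined.

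The balance of hairpin arms was compared over hairpins with at least 100 counts over both arms and libraries and at least 1 count per library on the minor arm, or with at least 1000 counts as an alternative. Where a mature microRNA has several hairpins, its whole count was used for each. Positions are on GRCh38, from GENCODE release 29, for the 1267 of 1917 precursors whose name was matched through the gene synonyms of a RefSeq table. The deposited table itself holds no coordinates. The alternatives were total count scaling, DESeq2 1.42.0 size factors, other abundance filters, a 1.5-fold rule, 5 CPM added to both values, the sum over precursor rows, other bins for the random lists, and thinning to equal depth.

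The scripts were tested on simulated counts for the comparison of shELOVL5 with shLuc. From the microRNAs with at least 50 real counts, 200 were changed by 3-fold, and 428 microRNAs had at least 50 simulated counts. The simulated ratios were scaled by the library totals, so the TMM step was not tested. The 2-fold rule recovered 100% of the 90 changed and expressed microRNAs and called 0 of the 104 unchanged ones. The simulated noise was Poisson counting error only, without variation between cultures. These figures therefore give no rate of false calls for unreplicated cultures. The 95% intervals held the true ratio for 96.3% of microRNAs. The list percentiles were tested on independent random log2 ratios with randomly drawn members, not on counts. That simulation does not cover lists whose members vary together. Of 200 simulated lists without a shift, 6.5% fell at or beyond the 2.5th or 97.5th percentile. With a log2 shift of 0.5, 95.5% lay at or above the 97.5th. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The table holds microRNAs and no ELOVL5 mRNA, so the knockdown itself was not checked here.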

Results

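MicroRNAs were profiled by small RNA sequencing in MDA-MB-231 breast cancer cells carrying an shRNA against ELOVL5 or the control shRNA shLuc, with 1 library of each. The libraries were of similar depth, with 6811811 microRNA counts in shELOVL5 and 7109272 in shLuc. At least 10 counts were found for 567 microRNAs in shELOVL5 and for 562 in shLuc. All ratios below are shELOVL5 over shLuc, with 95% counting intervals and no replicate check.

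Both libraries were dominated by the same abundant microRNAs. hsa-miR-100-5p was first, with 21.8% of the shELOVL5 counts (exact binomial 95% interval 21.8 to 21.9%) and 24.5% of the shLuc counts (24.5 to 24.6%). hsa-miR-21-5p, an oncogenic microRNA of many carcinomas, followed with 14.8% (14.8 to 14.8%) and 12.0% (11.9 to 12.0%). hsa-let-7i-5p, hsa-let-7a-5p, hsa-miR-221-3p, hsa-miR-222-3p, hsa-let-7f-5p and hsa-miR-26a-5p completed the 8 most abundant. Together these 8 took 60.9% of the counts in shELOVL5 and 60.5% in shLuc. Among the 8, the ratio was highest for hsa-miR-21-5p at 1.21 (1.20 to 1.21) and lowest for hsa-miR-100-5p at 0.868 (0.866 to 0.870). MIR100 lies on chromosome 11 at 122152229 to 122152308, in an intron of MIR100HG. MIR21 lies on chromosome 17 at 59841266 to 59841337, and overlaps an annotated exon of VMP1.

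The first comparison asked which microRNAs differed between cells with the ELOVL5 shRNA and control cells. Of 191 expressed microRNAs, 3 were at least 2-fold higher in shELOVL5 and 0 were at least 2-fold lower. The 3 were hsa-miR-504-5p and both arms of the miR-455 hairpin. hsa-miR-504-5p had 917 counts (133 CPM) in shELOVL5 and 7 counts (0.997 CPM) in shLuc, a ratio of 133 (64.5 to 333). Its size rests on the 7 control counts, and with 5 CPM added to both values the log2 ratio fell from 7.06 to 4.52. MIR504 lies on chromosome X at 138667711 to 138667793, in an intron of FGF13. hsa-miR-455-3p had 721 and 237 counts, a ratio of 3.10 (2.67 to 3.60). hsa-miR-455-5p had 808 and 351 counts, a ratio of 2.34 (2.06 to 2.66). MIR455 lies on chromosome 9 at 114209434 to 114209529, in an intron of COL27A1, a fibrillar collagen gene. All 3 were among the less abundant expressed microRNAs, and the count of 3 became 0 when a mean of at least 1000 CPM was required.

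At a 1.5-fold rule, 6 microRNAs were higher and 1 was lower. The additional ones that were higher were hsa-miR-146a-5p at a ratio of 1.84 (1.80 to 1.88), hsa-miR-146b-5p at 1.67 (1.57 to 1.78) and hsa-miR-200a-3p at 1.71 (1.47 to 1.99). miR-146a is known as an NF-kappaB-induced inhibitor of innate immune signalling. The 1 that was lower was hsa-miR-151a-3p, encoded in an intron of PTK2 on chromosome 8, which was 1.56-fold lower (1.55 to 1.58) with 85479 and 136053 counts. hsa-miR-146b-5p and hsa-miR-151a-3p lay outside the naming rule and were chosen after their values were seen. hsa-miR-210-3p, a hypoxia-induced microRNA, had a ratio of 1.47 (1.39 to 1.55). Most microRNAs differed little, with 153 of the 191 (80.1%) within 1.25-fold. Across the 191 microRNAs the log2 CPM of the libraries had a Pearson r of 0.978 and a Spearman rho of 0.989. These are correlations across microRNAs, which are not independent replicates.

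**Figure D1:**
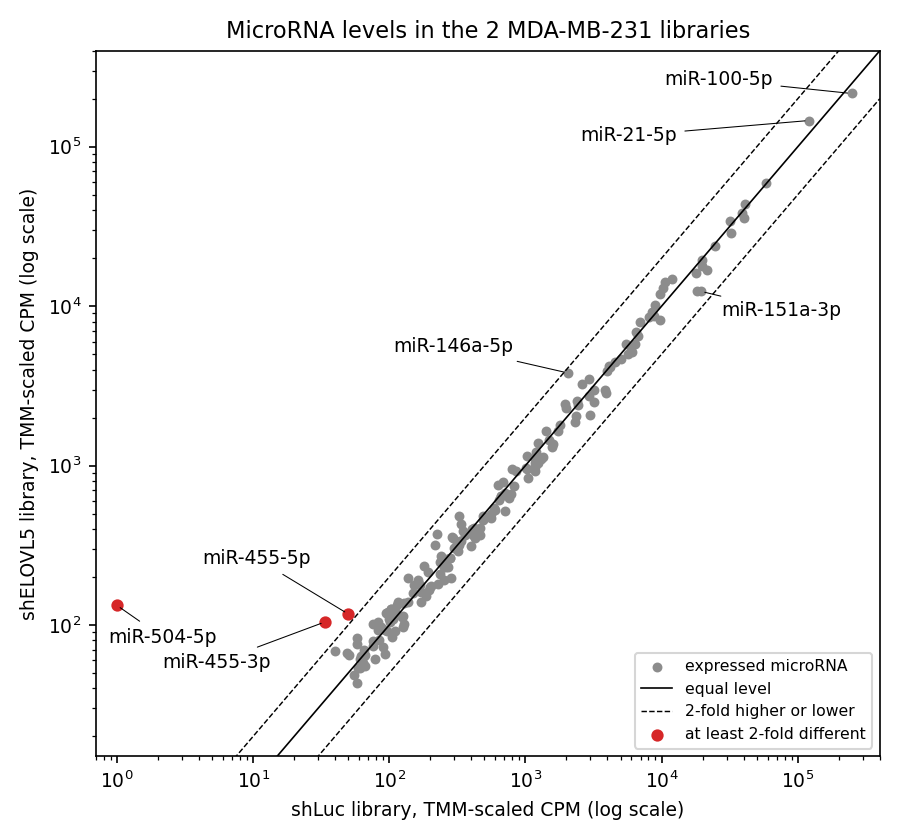
TMM-scaled CPM of the 191 expressed microRNAs in the shLuc library (x axis) against the shELOVL5 library (y axis), both on log scales, 1 library each. Each point is a microRNA, dashed lines mark 2-fold differences, and the 3 red points at least 2-fold higher in shELOVL5 are miR-504-5p and both miR-455 arms.

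The second comparison asked whether microRNA families and genomic clusters differed as groups. No expressed member of the families and clusters tested reached a 2-fold difference. In the list of the growth-promoting miR-17-92 cluster and its paralogs, 7 of 9 expressed members had a ratio whose interval lay above 1 and 2 had one below 1. hsa-miR-92a-3p was the most abundant at 1.33 (1.32 to 1.34), while hsa-miR-25-3p at 0.897 (0.885 to 0.909) and hsa-miR-93-5p at 0.938 (0.925 to 0.951), both from the miR-106b-25 cluster, were the ones below. The list's median log2 ratio was 0.29, an excess of 0.30 at percentile 99.5 of matched random lists. In the cluster of miR-183, miR-96 and miR-182, described in sensory organs and in carcinomas, all 3 members lay below 1. hsa-miR-183-5p was 1.42-fold lower, hsa-miR-182-5p 1.30-fold lower and hsa-miR-96-5p 1.09-fold lower. Their excess was -0.33, at percentile 1.74.

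In the miR-200 family, which maintains epithelial identity, hsa-miR-200b-3p stood at 1.31 (1.22 to 1.41), hsa-miR-200a-3p at 1.71 and hsa-miR-200c-3p at 0.981 (0.860 to 1.12). The family had an excess of 0.42, at percentile 91.1, from 3 expressed members, and lay at percentile 97.6 with the 4 members above a mean of 10 CPM. The miR-29 family, known repressors of collagen genes, had 2 expressed members and therefore no percentile, but lay at percentile 98.8 with the 3 members above a mean of 10 CPM. hsa-miR-29a-3p stood at 1.28 (1.27 to 1.30) and hsa-miR-29b-3p at 1.43 (1.32 to 1.56). The let-7 family, tumour-suppressive regulators of RAS and other growth genes, had a median close to level. Its 9 expressed members had a median log2 ratio of -0.0042 and an excess of 0.023, at percentile 76.0, with hsa-let-7i-5p at 1.00 (0.998 to 1.01), hsa-let-7a-5p at 1.07 and hsa-let-7f-5p at 1.09. Of the 9, 3 had intervals above 1 and 2 below, with the largest departure in hsa-let-7b-5p at 0.841 (0.829 to 0.853), named after its values were seen. The miR-30 family had an excess of 0.032, with hsa-miR-30a-5p at 0.970, hsa-miR-30d-5p at 0.896 and hsa-miR-30c-5p at 0.994. The miR-15/16 family, regulators of the cell cycle and BCL2, had an excess of 0.17 at percentile 79.2, with hsa-miR-16-5p at 1.16, hsa-miR-15b-5p at 0.993 and hsa-miR-424-5p at 1.09. In the miR-23/27/24 clusters, hsa-miR-27a-3p stood at 1.24 (1.23 to 1.25), hsa-miR-27b-3p at 0.772 (0.766 to 0.778) and hsa-miR-24-3p at 0.904. This list had an excess of -0.12, at percentile 22.4.

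The third comparison concerned lists chosen for the cell type and the target gene. Of the microRNAs known to suppress breast cancer metastasis, 4 of 11 were expressed. Of these, hsa-miR-146a-5p, hsa-miR-146b-5p and hsa-miR-126-3p had intervals above 1, the last at 1.20 (1.15 to 1.25), and hsa-miR-148b-3p had one below at 0.861 (0.838 to 0.885). The excess was 0.55, at percentile 99.8. Without hsa-miR-146b-5p, whose sequence is close to that of hsa-miR-146a-5p, it was 0.34 at percentile 96.1, an alternative chosen after seeing the data. The list known to promote migration and metastasis had 6 expressed members, 3 above and 3 below 1, with hsa-miR-21-5p at 1.21, hsa-miR-221-3p at 0.973 and hsa-miR-222-3p at 0.894. Its excess was 0.090, at percentile 78.7. The lipid metabolism list, fixed because ELOVL5 elongates fatty acids, had 8 expressed members. Of these, 3 had intervals above 1 and 3 below, with an excess of 0.012 at percentile 56.3. The most abundant were hsa-miR-27b-3p, hsa-miR-27a-3p and hsa-miR-30c-5p. The p53-induced list had 4 expressed members and an excess of 0.060 at percentile 68.5. In it, hsa-miR-107, which is also in the metastasis-promoting list, stood at 1.12, hsa-miR-192-5p at 0.938 and hsa-miR-34c-5p at 0.884. The p53 status of the cells was not examined, so this excess does not show whether p53 responded.

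Of the 12 lists given a percentile, 2 lay at or above the 97.5th and 1 at or below the 2.5th, where 0.6 would be expected by chance. This count depends on the expression limit, as the miR-200 and miR-29 families show. Members of 1 cluster may share a transcript, and members of a list cannot be taken as independent. These percentiles therefore describe the 2 libraries and are not tests of the knockdown.

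**Figure D2:**
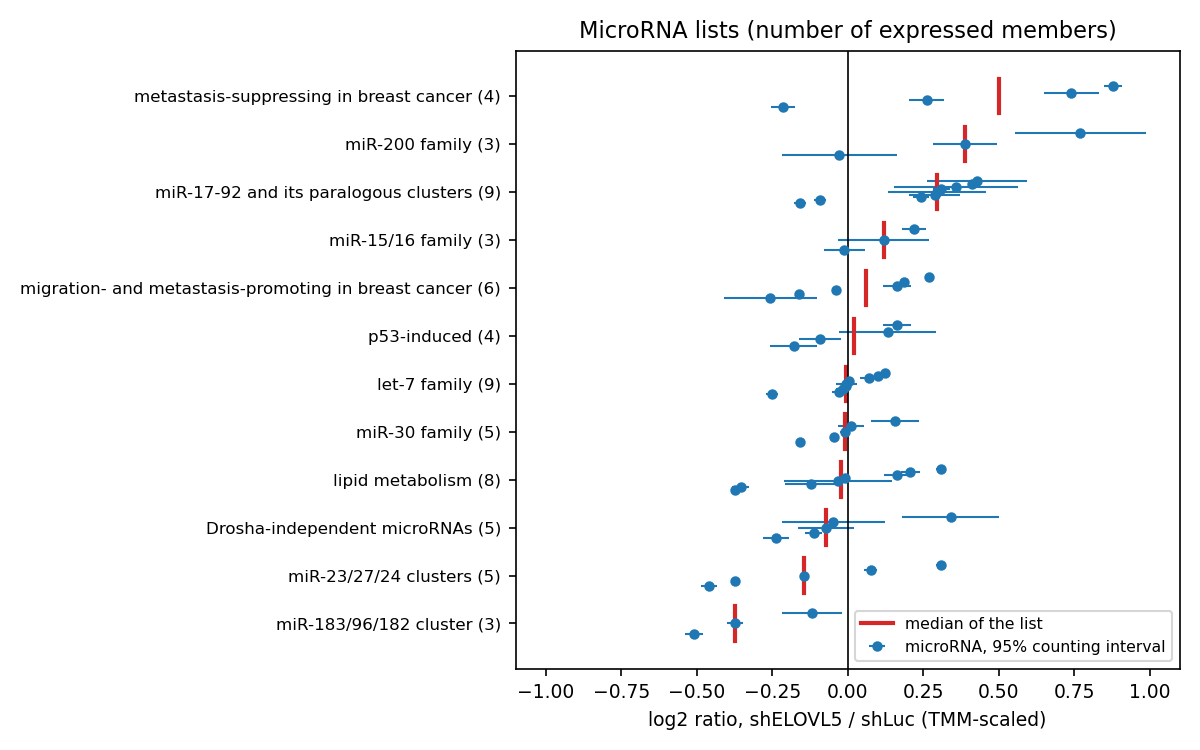
Log2 ratio of TMM-scaled CPM, shELOVL5 over shLuc (x axis), of each expressed member of the 12 lists with at least 3 expressed members (y axis, number of members in parentheses). Points are microRNAs with 95% counting intervals, red bars are list medians, and the medians run from -0.37 for the cluster of miR-183, miR-96 and miR-182 to 0.50 for the metastasis-suppressing list.

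The fourth comparison looked at microRNAs of other cell types and at microRNA processing. Most blood, stromal, liver, muscle and neuronal microRNAs lay below the expression limit in both libraries. Among blood cell markers only hsa-miR-486-5p was expressed, at 0.784 (0.740 to 0.829), and the summed list had 2282 counts in shELOVL5 and 2798 in shLuc, of which hsa-miR-486-5p gave 2146 and 2788. Below the expression limit, hsa-miR-142-5p had 84 and 6 counts (ratio 14.3, 6.28 to 39.9) and hsa-miR-142-3p 45 and 2 (ratio 22.9, 5.98 to 195). Among stromal and endothelial markers only hsa-miR-126-3p, which is also in the metastasis-suppressing list, was expressed, and the list had 5303 and 4497 counts, a ratio of 1.20 (1.15 to 1.25). Of these counts, hsa-miR-126-3p gave 5175 and 4394, so the summed ratio is nearly that of this microRNA alone. The liver, muscle, neuron and endocrine list had 232 and 209 counts and no expressed member. Its muscle microRNAs went opposite ways, with 155 and 69 counts for hsa-miR-206 (ratio 2.29, 1.71 to 3.08) and 14 and 80 for hsa-miR-1-3p (5.61-fold lower, 3.16 to 10.7). The imprinted 14q32 cluster had 5 and 1 counts over its 37 members, and the primate-specific C19MC cluster 521 and 335 over 18. Of the C19MC counts, hsa-miR-522-3p gave 309 and 246 and hsa-miR-516a-5p 99 and 56. hsa-miR-517a-3p and hsa-miR-517b-3p each had 8 and 1 counts and may share reads. hsa-miR-31-5p, a metastasis suppressor named after its values were seen, had 0 counts in both libraries, which allows up to 0.440 CPM in shELOVL5 and 0.422 CPM in shLuc. The members named here below the expression limit were likewise chosen after their values were seen.

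The list fixed as Drosha-independent holds mirtrons (microRNAs spliced from introns), the miR-320 family, miR-484 and miR-451a. miR-451a is known to be cut by Drosha and so does not belong in the list. It lay below the expression limit and did not enter the excess. Whether each other member is made without that nuclease was not checked. The list had 5 expressed members and an excess of -0.083 at percentile 24.8. Of these, 2 had intervals below 1 and 1 above, hsa-miR-877-5p at 1.27 (1.13 to 1.42), named after its values were seen. hsa-miR-320a-3p stood at 0.925 (0.908 to 0.943), hsa-miR-484 at 0.848 (0.823 to 0.875) and hsa-miR-320b at 0.951 (0.892 to 1.01). The arm balance was examined because an shRNA enters the same pathway as microRNA hairpins. Both libraries carried an shRNA, so the comparison cannot show whether an shRNA as such shifts the balance. Over 185 hairpins, the less abundant arm took a median of 3.97% of the hairpin's counts in shELOVL5 and 4.05% in shLuc. Over the 125 hairpins with at least 1000 counts the order turned, with 2.13% and 1.83%. The median log2 change of the minor-to-major ratio was 0.024 (counting interval -0.028 to 0.11), with 95 hairpins above 0 and 90 below.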

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

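No paired analysis was possible because each condition has 1 library, and for the same reason no library could be left out. The 3 microRNAs at least 2-fold higher and the 0 at least 2-fold lower stayed at 3 and 0 under total count scaling, DESeq2 size factors, 5 CPM added to both values, the sum over precursor rows, and when the whole counting interval had to lie beyond 2-fold. With a mean of at least 10 CPM the counts were 5 higher and 0 lower, the additional ones being hsa-miR-147b-3p (143 and 64 counts) and hsa-miR-206 (155 and 69 counts), chosen after their values were seen. With at least 1000 CPM they were 0 and 0 of 68 microRNAs, and with a 1.5-fold rule 6 and 1. With no filter beyond 1 count in each library they were 120 and 77 of 1024, where most microRNAs have few counts. Total count scaling shifted all log2 ratios by 0.036 and DESeq2 by -0.026, less than 0.1. The DESeq2 size factors were 1 and 1, so that setting amounts to the unscaled counts and is a weak check. With 5 CPM added to both values the log2 ratio of hsa-miR-504-5p was 4.52 against 7.06, since shLuc held under 1 CPM. Of 168 pairs of a named microRNA and a setting, 43 moved beyond the counting interval. Of these, 40 did so under the 2 scalings, which shift every log2 ratio by a constant, and 3 otherwise (hsa-miR-504-5p with 5 CPM added, hsa-miR-100-5p and hsa-miR-21-5p with the sum over precursor rows). The sign changed for hsa-let-7i-5p, hsa-miR-200c-3p, hsa-miR-30c-5p and hsa-miR-15b-5p, all near a ratio of 1 with intervals that include 1. The excess of the 12 lists is unaffected by scaling by construction. With a mean of at least 10 CPM it moved from 0.55 to 0.32 for the metastasis-suppressing list (percentile 98.4, 8 members) and from 0.090 to -0.0075 for the metastasis-promoting list (percentile 46.4, 7 members). At that setting the miR-200 family moved from percentile 91.1 to 97.6 (excess 0.49, 4 members) and the miR-29 family, with 3 members, lay at 98.8 (excess 0.28). Without hsa-miR-146b-5p the metastasis-suppressing list had 0.34, chosen after seeing the data. The miR-17-92 list without hsa-miR-106a-5p, also chosen after seeing the data, had 0.31. The Pearson r of the libraries was 0.987 with a mean of at least 10 CPM, against 0.978. Thinning shLuc to the depth of shELOVL5 left 555 microRNAs with at least 10 counts. Depth limits the rare microRNAs. The lack of replicate libraries limits every comparison, and no setting changes that.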

Other observations

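The tests of the shared transcript and of blood cell RNA and the comparison of hairpin arms were chosen after the result was seen. The microRNAs named here outside the naming rule, among them hsa-miR-142-5p and hsa-miR-1-3p, were also chosen after their values were seen. Members of 1 genomic cluster differed less from each other, on average, than shuffled members did. Over 14 clusters of hairpins within 10 kb, holding 32 expressed microRNAs with a single locus, the mean SD of the log2 ratio within a cluster was 0.14, against a median of 0.24 when memberships were shuffled. Each hairpin was represented by its more abundant expressed arm. The SDs were highest in the miR-99b, let-7e and miR-125a cluster on chromosome 19 (SD 0.27, log2 ratios from -0.56 to -0.028) and in the miR-200b and miR-200a pair on chromosome 1 (1167104 to 1167952), with an SD of 0.27 and the highest mean, 0.58. In the miR-30b and miR-30d pair the members lay on opposite sides of 1 (log2 ratios 0.16 and -0.16, SD 0.22). Some paralogous clusters stood on opposite sides of a ratio of 1. The miR-23b and miR-27b pair on chromosome 9 (95085208 to 95085541) had a mean log2 ratio of -0.42, and the miR-23a and miR-27a pair on chromosome 19 (13836440 to 13836659) had 0.19. The latter rests mainly on hsa-miR-27a-3p (log2 ratio 0.31, against 0.076 for hsa-miR-23a-3p), and the other arm, hsa-miR-27a-5p, stood at a ratio of 0.918 (0.888 to 0.950). The miR-17, miR-18a and miR-20a hairpins on chromosome 13 (91350605 to 91351135) had 0.28 with an SD of 0.035, and miR-25-3p, miR-93-5p and miR-106b-3p on chromosome 7 (100093560 to 100094074) had -0.11 with an SD of 0.041. The other arm of the last hairpin, hsa-miR-106b-5p, stood at a ratio of 1.22 (1.15 to 1.30), so the tight SD depends on the arm. Others stood on the same side, with the miR-99b cluster at -0.28 and the miR-99a and let-7c pair on chromosome 21 at -0.092. The side of that pair rests on hsa-miR-99a-5p (log2 ratio -0.18), since hsa-let-7c-5p was level (-0.0042).

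The observed SD lay at percentile 0.15 of the shuffled memberships, and at percentile 0.01 with the mean of a hairpin's expressed arms. Members of a cluster being made from a shared transcript is a candidate explanation, but these percentiles measure the coherence itself and do not test its cause. A GC trend between the libraries is not the whole source, since the percentile was 0.04 after the trend on hairpin GC content (r = -0.24 over hairpins) was removed. Another sequence-dependent bias stays open. Whether the cluster differences come from the knockdown, from other effects of the shRNA or from the cultures also stays open, as there was 1 library per group.

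The difference of hsa-miR-504-5p, 917 against 7 counts, was the largest among the expressed microRNAs, and both miR-455 arms followed. The linear trend on hairpin GC content, with a slope of -0.0068 log2 per GC percent, was too shallow to account for either. After removal of this trend the log2 ratio of hsa-miR-504-5p was 7.03 and the mean of the miR-455 arms was 1.39. The GC content of the mature arms was not examined. Whether another RNA that matches only the mature arm, such as a product of the introduced shRNA, could give the miR-504 reads stays open, because hsa-miR-504-3p had only 3 and 0 counts and the lower counting bound of its ratio was 0.42. For miR-455 both arms moved. The knockdown and a difference between cultures unrelated to it cannot be told apart with 1 library per group. Nor can loss of ELOVL5 be separated from other effects of its shRNA, as no other shRNA against ELOVL5 was compared.

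Below the expression filter, among 231 microRNAs with at least 50 counts over both libraries, 1 was at least 4-fold higher and 1 at least 4-fold lower. These were hsa-miR-142-5p, a microRNA of blood cells, with 84 and 6 counts (ratio 14.3, 6.28 to 39.9), and hsa-miR-1-3p, a muscle microRNA like hsa-miR-206, which was 5.61-fold lower with 14 and 80 counts (3.16 to 10.7). The other arm, hsa-miR-142-3p, had 45 and 2 counts. Blood cells rich in miR-223-3p, miR-150-5p, miR-451a or miR-144-3p, or their RNA, are an unlikely source of the miR-142 reads. Those microRNAs had 7 counts together in the shELOVL5 sample, with an upper 95% Poisson bound of 14.4. Of these, hsa-miR-451a gave 6, against 2 in shLuc, where the others had 0. hsa-miR-486-5p was 1.28-fold lower, but with 2146 and 2788 counts it could not show a small addition of blood cell RNA. These counts cannot speak to a blood cell type that is low in all of those markers. Expression in the cells themselves and reads carried over from another library were not tested.

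The arms of a hairpin agreed only in part. Over 74 hairpins with at least 200 counts on each arm, the log2 ratios of the arms had a Pearson r of 0.56 across hairpins and a Spearman rho of 0.34, and r was 0.36 without miR-455. Both arms lay on the same side of 1 in 48 of the 74. A mature microRNA with several hairpins, such as hsa-miR-181a-5p, entered with its whole count against the other arm of each. Such hairpins are not independent, and their shared arm cannot be split by hairpin. Counting error on arms with few counts can also lower the agreement. hsa-miR-151a-3p was 1.56-fold lower while hsa-miR-151a-5p stood at 0.977 (0.921 to 1.04).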
